A study of Mus musculus with 48 samples.

How the data were processed

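The deposited files give, per the labels, raw counts of reads per gene for each of 48 libraries. The unit is counts, and the values were checked to be whole numbers without exception. The authors' processing notes name FastQC 0.11.9, HISAT2 2.2.0, SAMtools 1.10 and featureCounts 2.0.0, and the mm10 mouse genome. The notes do not state the strand setting, the annotation release or any removal of duplicate reads. No reads were aligned here. The series design also mentions single-cell and spatial data, which are not analysed here.

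All 54735 genes in the deposited files were read, and genes with too few counts were removed with filterByExpr of edgeR, which left 17080 genes holding at least 99.9% of the counts of each library. Counts were scaled with TMM factors, and CPM values use the scaled library sizes. All 48 libraries entered a single edgeR quasi-likelihood fit (glmQLFit with robust estimation) with 1 coefficient per group. KCs after APAP were compared with the equal-weight mean of both PBS groups, LAM-like KCs with KCs of the same time, and the change of that difference between 36 and 48 h was tested as an interaction. The mean of the PBS groups is taken over log-scale coefficients, while CPM means are taken over libraries. A fold change against PBS can therefore differ from the ratio of the printed CPM means, most where the PBS groups differ or counts are low. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p below 0.05 was called. Log2 fold changes are given with their standard error (SE), and CPM as mean and standard deviation (SD) over libraries. As the same PBS libraries serve every time, the comparisons with PBS are not independent of each other.

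Lists of genes were written from general knowledge before the data were examined, 29 for programs of macrophages and 10 for markers of other cell types, and each was tested with camera of limma on voom values, with a preset correlation between genes of 0.01 and again with a correlation estimated from the data. Adjustment over the list alone uses only the p-values of the genes of that list. The comparisons, the threshold, the lists, the alternatives planned and the rule for naming genes were likewise fixed before the data were examined. A list of clock genes was made later, after clock genes were seen among the calls.

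Genes were named by this rule. For each LAM-like comparison, the 10 largest rises and 10 largest falls among called genes, with a mean of at least 10 CPM in the higher group and every library of the higher group above every library of the lower, were named. For each time of KCs the rule took 4 and 4, and for the interaction and the comparison of PBS groups 3 and 3. Predicted genes and segments of immunoglobulin and T cell receptor genes were passed over. A fixed set of 12 genes (Trem2, Spp1, Gpnmb, Cd9, Clec4f, Timd4, Vsig4, Marco, Ccr2, Ly6c2, Mki67 and Il1b) was named throughout, and members of the lists serve as examples. Single values of some list members are not reported here.

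Alternatives were DESeq2 in place of edgeR, its RLE scaling in place of TMM, no filter on low counts, each PBS group alone as the control, the replicate number as a block, a fit on the compared groups only, and each library left out in turn. After seeing the data, further alternatives were added: each set alone (for KCs against PBS with only PBS 24 h in set 1 and PBS 0 h in set 2 as the control), the set as a covariate, the hepatocyte marker sum as a covariate, both 48 h libraries numbered 4 left out, the replicate numbers of the file headers as a block, and the block together with an estimated correlation for the lists. The headers number both PBS 0 h libraries 3 and 4 where the labels give 1 and 2, so blocks by label and by header differ for KCs against PBS. Gene positions are those of GENCODE M21 on mm10. All 87 genes looked up were found, 3 overlap another gene on the same strand (Spp1, Serpinb2 and Dnaja1) and 18 overlap a gene on the other strand, among them Il1b, Mmp12, Nr1d1 and Dbp, whose counts are uncertain to that extent since the strand setting is not known.

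The procedure was tested on simulated negative binomial counts with the fitted means and spread of the real ones and known changes put in. Of genes given a 2-fold change, 49 of 67 were called in the comparison of LAM-like KCs at 36 h, 44 of 67 for KCs at 72 h and 32 of 67 between the PBS groups. Of those given a 1.5-fold change, 19, 25 and 7 of 67 were called, with 7, 7 and 0 false calls, where 16708, 16663 and 16709 genes were tested, the changed genes included. Draws were independent, so false calls from sets or replicate pairs were not tested, nor was recovery by count level. Except between PBS groups, calls were also counted for other splits of the compared libraries into groups of the same sizes. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.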

Results

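Gene expression was compared in macrophages isolated from the livers of male C57BL/6 mice given acetaminophen (APAP), a drug whose reactive product can kill hepatocytes. Kupffer cells (KCs), the resident macrophages of the liver, were profiled at 6, 12, 24, 36, 48, 72, 96, 120 and 168 h after APAP, and at 0 and 24 h after saline (PBS). At 36 and 48 h the labels give a second population, LAM-like KCs, named after lipid-associated macrophages (LAMs). The sample titles do not give the criterion that separated them from KCs. Nor do they say whether KCs of the other times still held such cells, so the KC population may differ between times. The 48 libraries formed 13 groups, with 4 libraries in each APAP group and 2 in each PBS group. Per library, 1.59e+07 to 2.61e+07 reads were counted in genes, and 17080 genes were tested. The labels do not say whether libraries come from separate animals, so the p-values measure the spread between samples. Sample numbers in file headers name no sets. They were cut here after 25 into set 1 (25 libraries, mostly replicates 1 and 2) and set 2 (23, mostly replicates 3 and 4). Results within sets are given beside pooled ones. PBS 24 h lies wholly in set 1 and PBS 0 h in set 2, so for KCs against PBS a fit on 1 set also changes the control group.

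In KCs of PBS mice the most abundant of the fixed marker genes was Clec4f, a lectin made by KCs (chromosome 6, 83644542 to 83656187, minus strand), at 14796 ± 1319 (SD, n = 4) CPM (counts divided by the scaled library size). Vsig4, a complement receptor of resident macrophages, was measured at 3826 ± 298 (SD, n = 4) CPM, and Timd4, a receptor for phosphatidylserine on dying cells (chromosome 11, 46810800 to 46844332, plus strand), at 1207 ± 52.8 (SD, n = 4) CPM. The scavenger receptor gene Marco (chromosome 1, 120474538 to 120505024, minus strand) stood at 522 ± 166 (SD, n = 4) CPM and the inflammatory cytokine gene Il1b at 433 ± 232 (SD, n = 4) CPM. Some LAM markers were low in these libraries. Trem2, a lipid-sensing receptor (chromosome 17, 48346401 to 48354147, plus strand), was at 31.3 ± 11.9 (SD, n = 4) CPM, the lysosomal glycoprotein gene Gpnmb (chromosome 6, 49036546 to 49070929, plus strand) at 1.27 ± 0.617 (SD, n = 4) CPM, and Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050, plus strand), at 0.346 ± 0.294 (SD, n = 4) CPM. The monocyte genes Ccr2 and Ly6c2 were at 4.67 ± 1.47 (SD, n = 4) and 0.139 ± 0.112 (SD, n = 4) CPM, and neither passed the threshold in any comparison.

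**Figure D1:**
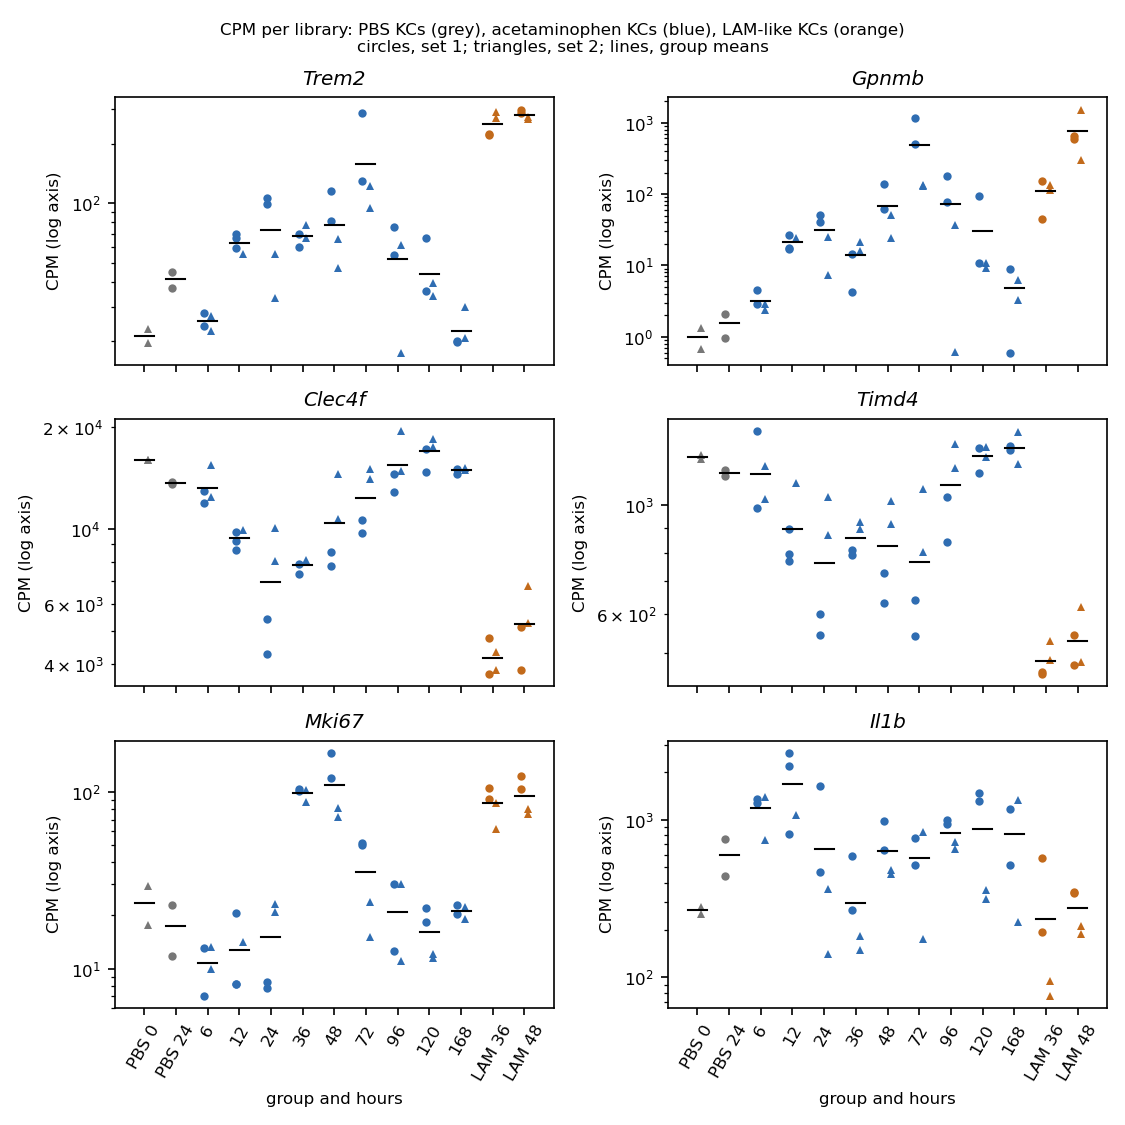
CPM on a log axis of Trem2, Gpnmb, Clec4f, Timd4, Mki67 and Il1b in each of the 48 libraries, by group, with 1 point per library. Trem2 lies between 220 and 297 CPM in the LAM-like libraries of both times and up to 116 CPM in the KC libraries of the same times.

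To identify how LAM-like KCs differed from KCs taken at the same time, both populations were first compared at 36 h, where 322 genes differed, 132 higher and 190 lower in LAM-like KCs. Cd36, a receptor that takes up fatty acids and oxidised lipoproteins (chromosome 5, 17781690 to 17888801, minus strand), rose by 2.6 ± 0.30 (log2 fold change ± SE, adjusted p = 5.05e-07), from 318 ± 114 (SD, n = 4) to 1926 ± 456 (SD, n = 4) CPM. Trem2 rose by 1.88 ± 0.33 (adjusted p = 0.000422), from 68.2 ± 7.16 (SD, n = 4) to 250.4 ± 34.1 (SD, n = 4) CPM. Other rises were those of Nrp2 at 3.10 (neuropilin 2, adjusted p = 0.00123), the chemokine gene Cxcl14 at 2.25 (adjusted p = 6.89e-05), Olfml3 at 2.2 (adjusted p = 2.17e-05) and the aldo-keto reductase gene Akr1b8 at 2.34 (adjusted p = 0.000702). C6, a component of the complement pore, fell by 2.61 (adjusted p = 3.70e-07), from 369.6 ± 24.1 (SD, n = 4) to 60.6 ± 8.99 (SD, n = 4) CPM, and the eosinophil-attracting chemokine gene Ccl24 fell by 2.5 (adjusted p = 1.27e-06). Ifitm6 and Plac8, found in monocytes, fell by 3.24 (adjusted p = 9.64e-08) and 3.05 (adjusted p = 2.79e-05). Clec4f fell by 0.91 (adjusted p = 0.00248), from 7823 ± 327 (SD, n = 4) to 4161 ± 479 (SD, n = 4) CPM, and Timd4 by 0.83 (adjusted p = 0.00393).

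Of the genes that differed at 36 h, 53 were at least 2-fold higher and 99 at least 2-fold lower. LAM-like and KC libraries that share a replicate number were correlated in their residuals (0.447 to 0.643, against -0.545 to 0.477 for other numbers), and a model with the number as a block gave 1740 genes, 762 higher and 978 lower. Within sets, 203 genes were called in set 1 and 324 in set 2. The count fell to 197 without KC 36 h replicate 2, to 179 without LAM-like 36 h replicate 1 and to 206 without LAM-like 36 h replicate 3.

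Of the other genes named by the rule for 36 h, Cd63, a lysosomal tetraspanin, rose by 2.40 (adjusted p = 0.0151), and Cd63-ps, a near copy whose reads cannot be told from those of Cd63 with certainty, by 2.57 (adjusted p = 0.00506). Without KC 36 h replicate 1 or 2 the adjusted p of Cd63 was 0.0548 or 0.0839. Clec5a, a receptor of myeloid cells, rose by 2.27 (adjusted p = 0.00145), with an adjusted p of 0.0540 in set 1 alone and 0.0856 in set 2 alone. Itgax, the integrin CD11c, rose by 2.01 (adjusted p = 0.0130), with 0.0511 without KC 36 h replicate 2, 0.0710 without KC 36 h replicate 4 and 0.0579 without LAM-like 36 h replicate 1. Atp8b4 rose by 2.28 (adjusted p = 0.0207), and its adjusted p was 0.0522 to 0.0796 without any 1 of KC 36 h replicates 1, 2 and 3 and LAM-like 36 h replicates 1 and 4. Enpp2 (autotaxin) was at -2.65, Ptgis (prostacyclin synthase) at -2.16, Adamdec1 at -2.12 and Adcy4 at -2.06. Gbp2b, induced by interferon, fell by 2.75 (adjusted p = 0.0202), with 0.0542 to 0.0906 without any 1 of KC 36 h replicates 3 and 4 and LAM-like 36 h replicates 1, 3 and 4. Rims4 fell by 1.93 (adjusted p = 0.0127), with 0.0608 without LAM-like 36 h replicate 3. Of the fixed genes, Gpnmb did not pass at 36 h (3.0, adjusted p = 0.0883, 112 ± 47.4 (SD, n = 4) against 13.9 ± 7.10 (SD, n = 4) CPM) but passed with the block (adjusted p = 6.69e-05). Cd9 likewise passed only with the block, at 0.98 (adjusted p = 0.000463, against 0.228 without it), as did Il1b at -0.61 (adjusted p = 0.0112, against 0.911). Spp1 (0.82), Vsig4 (0.11), Marco (-0.12), Ccr2 (-0.53) and the proliferation gene Mki67 (-0.19) did not pass, and Ly6c2 had 3 reads in all LAM-like libraries of this time.

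By gene list, the LAM program moved up at 36 h. If LAM markers served to separate the populations, a rise of LAM genes at 36 or 48 h would follow from the separation itself. Of its 29 measured genes, 12 rose and none fell, among them Lpl (0.98), Anxa2 (0.95) and the lipid droplet gene Plin2 (0.85), and 17 did not pass. Adjusted over the list alone, 21 rose, and the list as a whole shifted up (camera, adjusted p = 1.05e-24, and adjusted p = 0.0127 with an estimated correlation). With the block and an estimated correlation together it had 0.0637, and 0 of the 39 lists passed at 36 h, at 48 h or in the test of the change between them. KC identity genes moved the other way, with 7 of 23 down and 0 up (9 down adjusted over the list alone), including the transcription factor gene Spic (-1.39) and the iron exporter gene Slc40a1 (-1.13). That shift had an adjusted p of 1.77e-09, and 0.0116 with an estimated correlation. Iron and haem genes fell in 4 of 18 (2 up and 9 down adjusted over the list alone), with Hmox1 at -1.28, Ncoa4, the receptor that sends ferritin to lysosomes, at -1.04 and Blvrb at -0.70 (adjusted p = 9.12e-05, and 0.0116 with an estimated correlation). Monocyte genes fell in 3 of 16, Ifitm6 and Plac8 among them, and their shift was kept with an estimated correlation (adjusted p = 0.00139, then 0.0116). In the complement list 4 genes rose, C5ar1 (1.37), C3ar1 (1.26), Itgam (1.12) and Itgax, and 2 fell, C6 and Cfp (-0.69), so the list did not shift (adjusted p = 0.586). Genes for the clearance of dead cells rose in 4 of 18 (Cd36, Stab1 1.34, Gas6 0.99, Itgb5 0.63) and fell in 1 (Timd4), with a shift up only under the preset correlation (adjusted p = 0.00659, and 0.153 with an estimated correlation).

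Further lists shifted at 36 h only under the preset correlation. Type I interferon genes had a median of -0.42 with 2 of 29 down, Irf7 (-0.83) and Ifi203 (-0.82), and 10 down adjusted over the list alone (adjusted p = 4.24e-09, and 0.216 with an estimated correlation). MHC class II and class I genes each had 1 fall, Cd86 (-0.82, adjusted p = 0.00343 for the list, and 0.399 with an estimated correlation) and H2-T23 (-0.69, adjusted p = 0.00109, and 0.354 with an estimated correlation). Glycolysis genes shifted up with 0 of 24 passing over all genes and 6 adjusted over the list alone (adjusted p = 4.76e-06, and 0.184 with an estimated correlation). Matrix genes shifted up with Timp2 (0.46) as the 1 riser (adjusted p = 0.00139, and 0.216 with an estimated correlation). Ribosomal protein genes (adjusted p = 0.00521), p53 targets (0.0121), inflammatory genes (0.0447) and lysosome genes (0.0485) shifted up and mitochondrially encoded genes down (0.0447), with 0.670, 0.152, 0.719, 0.670 and 0.670 in that order with an estimated correlation. With the block the inflammatory shift had an adjusted p of 3.11e-07 and the mitochondrially encoded one 0.000742, against 0.114 and 0.397 with an estimated correlation added. Of lists for other cell types, the hepatocyte list had a median of -1.14 with 1 of 24 down, Trf (-1.09), and its summed level was 871 ± 335 (SD, n = 4) CPM against 1948 ± 469 (SD, n = 4) CPM in KCs (adjusted p = 1.07e-08, and 0.362 with an estimated correlation). B and plasma cell genes fell in 2 of 14, Ighd (-3.70) and Iglc2 (-3.52) (adjusted p = 1.39e-06, and 0.0556 with an estimated correlation). Stellate cell genes fell in 2 of 17, Colec11 (-2.78) and Rgs5 (-2.58) (adjusted p = 0.0121, and 0.605 with an estimated correlation). Erythroid and capsular macrophage genes shifted down (adjusted p = 0.00659 and 0.0467, and 0.30 and 0.399 with an estimated correlation). Endothelial genes fell in 3 of 20, Pecam1 (-1.42), Cdh5 (-0.56) and Stab2 (-0.39), while the median of the list was 0.50, its mean 0.33 and its test pointed down (adjusted p = 0.434). Pf4, a platelet gene, rose by 1.32.

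With the replicate number as a block, counts of called genes at 36 h grew in most lists. The Lipid-associated macrophage list then had 22 up and 1 down, Kupffer cell identity 2 up and 13 down, Monocyte 2 up and 7 down, and Type I interferon response 17 down. MHC class II presentation had 5 down, MHC class I presentation 6 down, Lysosome 8 up and 3 down, NRF2 targets 2 up and 6 down, and Haem and iron handling 2 up and 10 down. Clearance of dead cells had 8 up and 3 down, Complement 4 up and 6 down, Matrix remodelling 9 up, Alternative activation 1 up and 3 down, and Fatty acid oxidation and PPAR targets 4 up and 1 down. All 24 genes of the Hepatocyte list were then lower, as were 7 of the Stellate cell and fibroblast list.

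At 48 h LAM-like KCs differed from KCs in 429 genes, with 195 higher and 234 lower. Cd36 rose by 1.96 ± 0.30 (adjusted p = 9.35e-05), from 395 ± 26.2 (SD, n = 4) to 1535 ± 122 (SD, n = 4) CPM, and Trem2 by 1.85 ± 0.33 (adjusted p = 0.000794), from a mean of 77.5 to 280.0 ± 14.5 (SD, n = 4) CPM. Gpnmb rose by 3.47 ± 0.92 (adjusted p = 0.0326), from 68.8 ± 49.5 (SD, n = 4) to 766 ± 529 (SD, n = 4) CPM. Further rises were in Fabp5, a fatty acid carrier (2.10, adjusted p = 0.00591), Cd63 (2.64, adjusted p = 0.00824) with its near copy Cd63-ps (2.56), the signalling adaptor gene Blnk (1.93, adjusted p = 0.00990) and Lgals1, galectin 1 (1.86, adjusted p = 0.0112). Plac8 and Ifitm6 fell by 2.99 (adjusted p = 6.64e-05) and 2.09 (adjusted p = 5.08e-05), and Adamdec1, a protease of tissue macrophages, by 2.22 (adjusted p = 2.22e-05). Gfra2, a receptor for neurturin, fell by 2.08 (adjusted p = 0.000158), Asb2 by 1.97 (adjusted p = 0.00117) and Vipr1, a receptor for vasoactive intestinal peptide, by 2.12 (adjusted p = 0.00678). Clec4f fell by 0.98 (adjusted p = 0.00154), from 10393 ± 3043 (SD, n = 4) to 5253 ± 1205 (SD, n = 4) CPM, although a fit on the compared groups alone gave an adjusted p of 0.0550.

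Of the 429 genes, 42 were at least 2-fold higher and 121 at least 2-fold lower. The block by replicate number gave 2054 genes, 969 higher and 1085 lower, while set 1 alone gave 210 and set 2 alone 352. The count fell to 173 without KC 48 h replicate 3, 149 without KC 48 h replicate 4, 163 without LAM-like 48 h replicate 1 and 196 without LAM-like 48 h replicate 2. Leaving out both libraries numbered 4 gave 141 genes. It also ended the calls of Gpnmb (2.77, adjusted p = 0.223), Cd63 (adjusted p = 0.0908), Cd63-ps (0.0820), Fabp5 (0.0628), Blnk (0.0747) and Lgals1 (0.0842). Single libraries were enough for some of these. Gpnmb had an adjusted p of 0.0572 to 0.126 without any 1 of KC 48 h replicates 2, 3 and 4 and LAM-like 48 h replicates 1, 2 and 4, Blnk had 0.0550 without KC 48 h replicate 4, and Lgals1 had 0.0577 and 0.0664 without KC 48 h replicates 3 and 4.

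Of the remaining named genes of 48 h, Atp6v0d2, a subunit of the vacuolar proton pump, rose by 2.5 (adjusted p = 0.0471), with 0.0768 to 0.153 without any 1 of KC 48 h replicates 2, 3 and 4 and LAM-like 48 h replicates 1, 2 and 4. Nrp2 rose by 2.28 (adjusted p = 0.0226), with 0.0508 to 0.0938 without any 1 of KC 48 h replicates 3 and 4 and LAM-like 48 h replicates 1 and 2. Pqlc3 rose by 2.09 (adjusted p = 0.0357), with 0.0681 to 0.151 without any 1 of KC 48 h replicates 2, 3 and 4 and LAM-like 48 h replicates 1 and 2. Colec11, a lectin made by stellate cells, fell by 2.65 (adjusted p = 0.0108), with 0.0666 without LAM-like 48 h replicate 1. Gbp2b fell by 2.71 (adjusted p = 0.0224), with 0.0598 to 0.119 without any 1 of KC 48 h replicates 3 and 4 and LAM-like 48 h replicates 1 and 2. Rgs5, a pericyte gene, and Sod3 fell by 2.14 (adjusted p = 0.0392) and 2.10 (adjusted p = 0.0340). With the hepatocyte marker sum as a covariate they stood at -1.43 (adjusted p = 0.131) and -1.18 (adjusted p = 0.181), and Rgs5 had 0.0577 to 0.166 without any 1 of 7 libraries, all but LAM-like 48 h replicate 4, and Sod3 0.0697 to 0.127 without any 1 of 6, all but KC 48 h replicate 3 and LAM-like 48 h replicate 4. Timd4 fell by 0.64 (adjusted p = 0.0353), with 0.0755 to 0.194 without any 1 of KC 48 h replicates 3 and 4 and LAM-like 48 h replicates 1, 2 and 4. Spp1 (1.89, adjusted p = 0.353), Cd9 (1.12, adjusted p = 0.124) and Il1b (-1.22, adjusted p = 0.398) passed only with the block, with adjusted p of 0.00243, 0.000142 and 0.000103. Vsig4 (0.07), Marco (-0.24), Ccr2 (0.87) and Mki67 (-0.21) did not pass.

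Of 29 LAM genes, 15 rose at 48 h and 0 fell, with Clec7a (1.1) and Cstb (0.71) among them, and 23 rose and 1 fell adjusted over the list alone (adjusted p = 6.90e-27, 0.0327 with an estimated correlation, and 0.0611 with the block as well). Lysosome genes rose in 8 of 31 (13 adjusted over the list alone), among them the galactosidase gene Gla (1.18) and the protease gene Ctsd (0.96), and the list shifted up with an adjusted p of 1.16e-12, but not with an estimated correlation (0.131). Glycolysis genes rose in 4 of 24, including Pgam1 (0.73) and Pkm (0.65) (adjusted p = 8.26e-05, and 0.271 with an estimated correlation). Oxidative phosphorylation genes rose in 4 of 31, Atp5b (0.40), Ndufs1 (0.36), Atp5a1 (0.31) and Sdha (0.30) (adjusted p = 3.23e-08, and 0.283 with an estimated correlation). Fatty acid oxidation genes were up in 3 of 21, Cd36, Hadha (0.35) and Acadl (0.33) (adjusted p = 0.000112, and 0.242 with an estimated correlation). The growth factor genes Vegfb (0.98) and Tnfsf12 (0.90) rose, in a list whose median was 0.10, whose mean was -0.23 and whose test pointed up (adjusted p = 0.218).

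KC identity genes fell in 4 of 23 at 48 h, C6 (-1.48), Clec4f, Cdh5 (-0.74) and Timd4 (adjusted p = 2.2e-07, and 0.0758 with an estimated correlation). Complement genes fell in 4 of 16, C6, Cfb (-1.27), C4b (-0.90) and Cfp (-0.64), and rose in 2, Itgax (1.75) and C3ar1 (0.75) (adjusted p = 0.00302, and 0.283 with an estimated correlation). Type I interferon genes fell in 2 of 29, Oas2 (-0.92) and Irf7 (-0.82), and in 17 adjusted over the list alone (adjusted p = 1.83e-13, and 0.166 with an estimated correlation). Cd86 (-0.73) and H2-T23 (-0.62) were again the 1 fall of the MHC class II and class I lists (adjusted p = 0.000478 and 8.26e-05, and 0.283 and 0.269 with an estimated correlation). Hmox1 (-1.05) and Blvrb (-0.64) fell among haem and iron genes, whose shift reached an adjusted p of 0.0528 and passed with the block (0.0136), but not with an estimated correlation as well (0.137). The block also brought past the threshold the shifts down of immediate early genes (8.61e-06), monocyte genes (0.0204) and alternative activation genes (0.0311) and the shift up of p53 targets (0.0136). With an estimated correlation as well these had 0.318, 0.272, 0.258 and 0.137. Unfolded protein response genes (median 0.27, adjusted p = 0.000478) and matrix genes (0.33, adjusted p = 0.0133) shifted up with 0 passing over all genes in edgeR, and had 0.332 and 0.301 with an estimated correlation. Mitochondrially encoded genes shifted down (adjusted p = 0.00873, and 0.467 with an estimated correlation) and ribosomal protein genes up, with Rps2 (0.41) as the 1 riser (adjusted p = 0.00415, and 0.624 with an estimated correlation). The hepatocyte list had a median of -1.09 with Trf (-0.83) as its 1 fall (adjusted p = 1.89e-07, and 0.332 with an estimated correlation). Stellate cell genes fell in 4 of 17, Colec11, Pdgfrb (-2.30), Rgs5 and Des (-2.13) (adjusted p = 0.000478, and 0.332 with an estimated correlation). Single falls in other cell type lists were S100a9 (-3.51), Hbb-bs (-2.54), Iglc2 (-3.68) and Ptgis (-1.16), and Pf4 rose by 1.05. Shifts down of B and plasma cell (adjusted p = 0.000147), capsular macrophage (0.00873), erythroid (0.0149) and T and NK cell genes (0.0339) had 0.242, 0.269, 0.295 and 0.332 with an estimated correlation.

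List counts were mostly higher in the block fit at 48 h too. The Lipid-associated macrophage list had 23 up and 1 down, Kupffer cell identity 14 down, Monocyte 2 up and 5 down, Type I interferon response 22 down, MHC class II presentation 7 down and MHC class I presentation 8 down. Lysosome had 18 up and 1 down, Glycolysis and hypoxia 9 up, Oxidative phosphorylation 11 up, Fatty acid oxidation and PPAR targets 7 up, Growth factors 5 up and 1 down, and Ribosomal proteins 2 up. NRF2 targets had 2 down, Haem and iron handling 5 up and 9 down, Complement 2 up and 9 down, and Alternative activation 5 down. Of other cell types, the Hepatocyte list had 23 of 24 down, Stellate cell and fibroblast 7 down, Capsular and peritoneal macrophage 5 down, Erythroid 2 down, and Neutrophil 1 up and 2 down.

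The differences between LAM-like KCs and KCs at both times were set side by side. Over all genes their fold changes had a Pearson r of 0.257 and a Spearman rho of 0.405. Of the risers 57 were shared, against 1.51 for independent lists of these lengths, and of the fallers 100 were shared, against 2.6. Of the 594 genes called at either time, 573 had the same sign at both and 0 were called in opposite directions. A test of the change in the difference between 36 and 48 h called 1 gene in edgeR, against 592 at an unadjusted p below 0.05 and 5 called by DESeq2. That gene was Ncoa4 (chromosome 14, 32159865 to 32179855, plus strand), with a change of 1.12 ± 0.19 (adjusted p = 0.0136). It was at 127 ± 6.70 (SD, n = 4) CPM in LAM-like KCs and 261 ± 18.5 (SD, n = 4) CPM in KCs at 36 h, and at means of 355 and 337 CPM at 48 h. The change was 1.28 (adjusted p = 0.372) in set 1 and 0.98 (adjusted p = 0.550) in set 2, and the call ended without KC 36 h replicate 2 (adjusted p = 0.0666), KC 48 h replicate 2 (0.0652), LAM-like 36 h replicate 1 (0.0566) or LAM-like 36 h replicate 4 (0.0577), which leaves 0 genes called. The block by number gave 43 genes, 19 up and 24 down. By list, lysosome (median 0.22, adjusted p = 4.35e-08), oxidative phosphorylation (0.15, adjusted p = 2.39e-07) and unfolded protein response genes (0.19, adjusted p = 0.00177) shifted further up at 48 h than at 36 h under the preset correlation, and none did with an estimated correlation (0.528, 0.958 and 0.958).

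**Figure D2:**
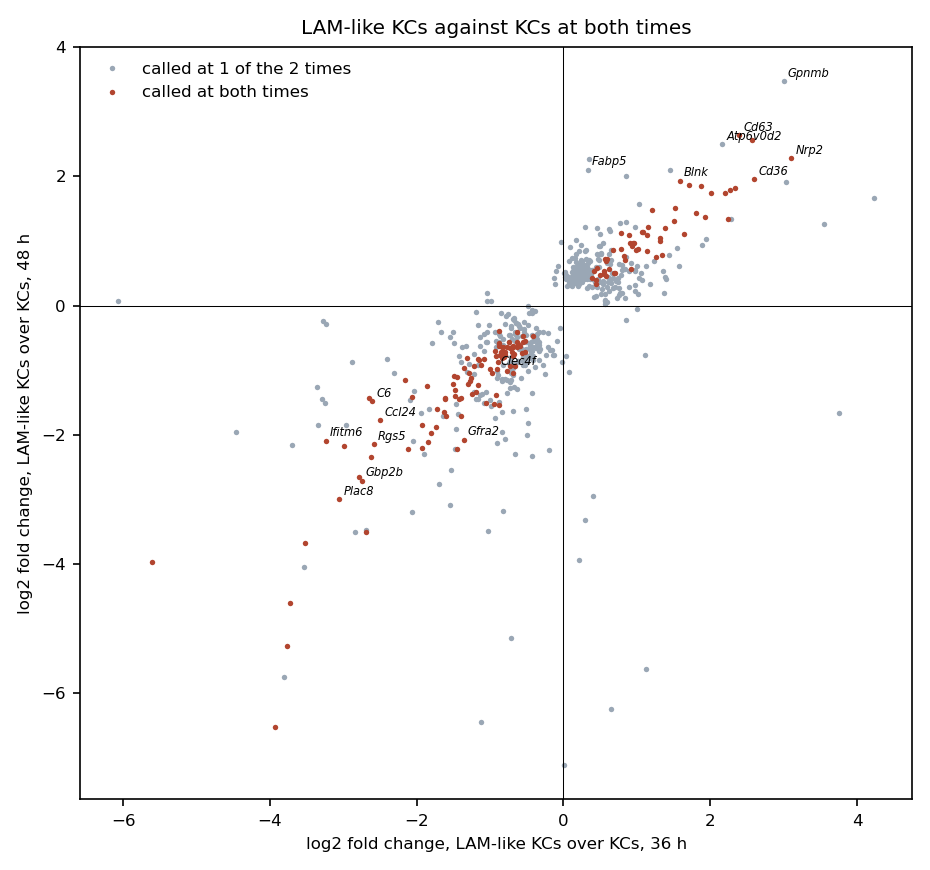
Log2 fold change of LAM-like KCs over KCs at 36 h (horizontal axis) against 48 h (vertical axis), 1 point per gene called at either time, with those called at both times in red. Of the 594 called genes, 573 lie on the same side of 0 at both times.

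**Figure D3:**
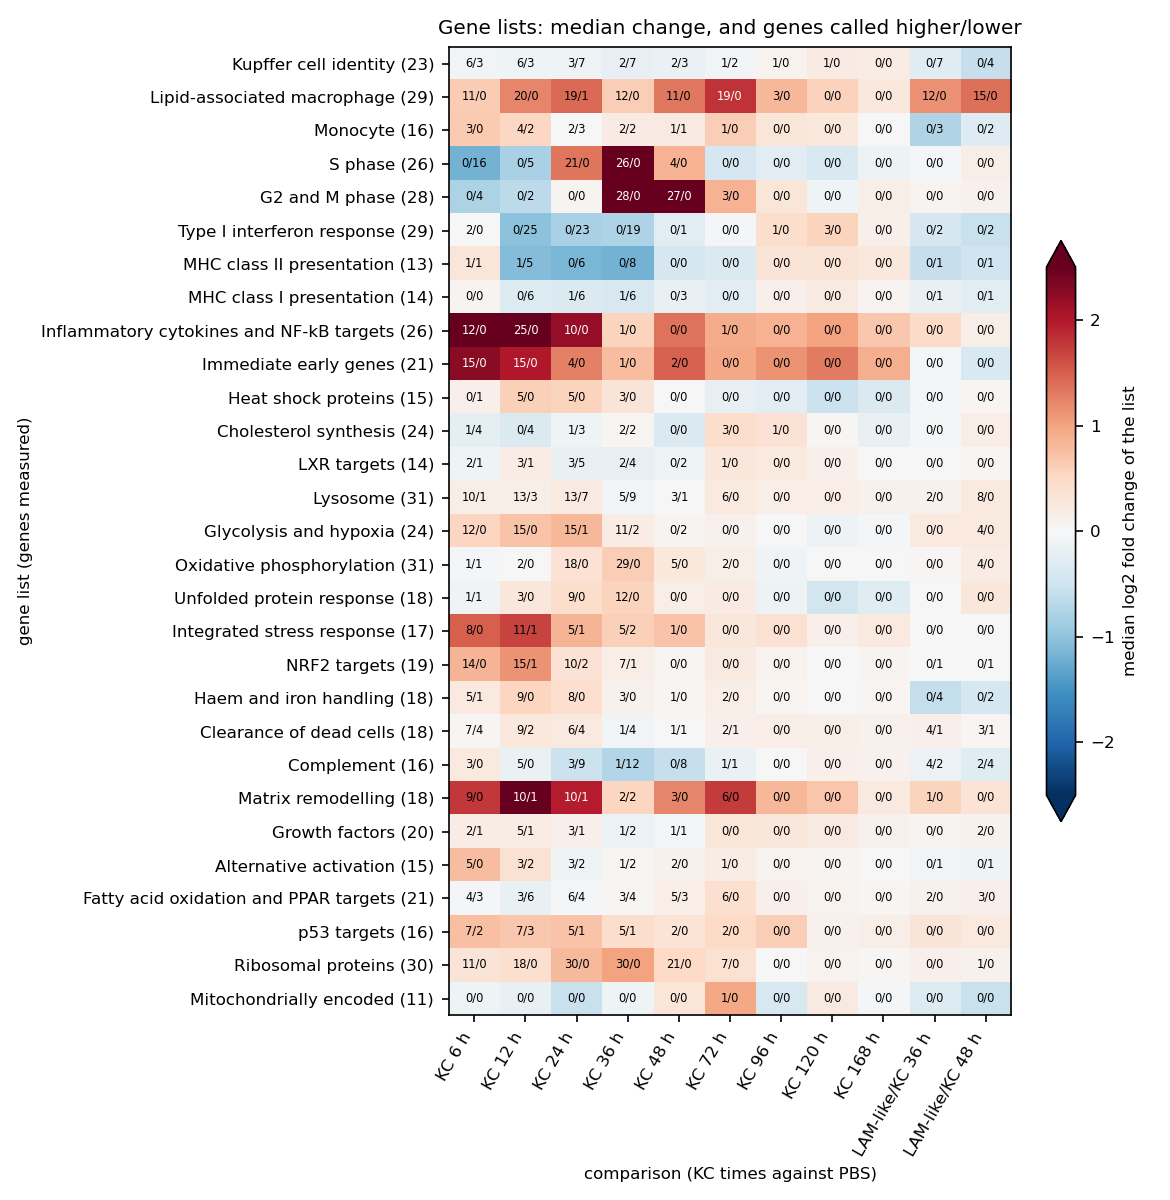
Median log2 fold change of each of the 29 program lists (lines) in each comparison (columns) as colour, with the number of genes up and down printed in the cell. The LAM list is up with 12, 15, 11, 20, 19, 12, 11 and 19 genes in the LAM-like comparisons and at 6 to 72 h in KCs, where S phase genes go from 16 down at 6 h to 26 up at 36 h. At 36 and 48 h LAM-like KCs were profiled apart, so KCs of those times may not match KCs of other times.

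KCs after APAP were next compared with the mean of both PBS groups. That mean is on the log scale, so fold changes can differ from the ratio of the CPM means printed beside them. At 6 h 2586 genes differed, 1661 up and 925 down. Cxcl3, a neutrophil attractant, rose by 9.02 (adjusted p = 0.000665), from 0.0641 ± 0.128 (SD, n = 4) to 14.6 ± 15.8 (SD, n = 4) CPM, and the metallothionein gene Mt2 by 8.25 (adjusted p = 4.00e-07), from 0.0873 ± 0.0833 (SD, n = 4) to 21.3 ± 32.2 (SD, n = 4) CPM. Trem1, which amplifies inflammatory signals, rose by 8.11 (adjusted p = 0.000527) and Ddit4, an inhibitor of mTOR, by 7.68 (adjusted p = 0.000261), with 0.215 and 0.152 in set 2 alone. Marco rose by 1.98 (adjusted p = 5.99e-05), to 2039 ± 492 (SD, n = 4) CPM. The largest falls were in genes of hepatocytes, the lipogenic gene Thrsp (-4.81, adjusted p = 0.00376), Mup17, a major urinary protein with near-identical relatives (-4.73, adjusted p = 0.0143), Rgn (-3.56, adjusted p = 0.00161) and the carbonic anhydrase gene Car3 (-3.50, adjusted p = 0.00520). In set 2 alone Thrsp, Mup17 and Car3 did not pass (0.182, 0.179 and 0.114). Il1b was higher without passing (1.58, adjusted p = 0.0954, 1196 ± 307 (SD, n = 4) CPM), and Trem2, Spp1, Gpnmb, Cd9, Clec4f, Timd4, Vsig4 and Mki67 did not pass.

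Inflammatory genes rose at 6 h in 12 of 26 with 0 down (22 adjusted over the list alone), among them Clec4e (4.92) and the chemokine gene Cxcl2 (4.40), and the list shifted up (adjusted p = 2.88e-09, and 0.450 with an estimated correlation). Immediate early genes rose in 15 of 21, with Fosb at 3.42 (adjusted p = 2.87e-07, and 0.538 with an estimated correlation). All 21 immediate early genes (median 1.90) and 20 of 26 inflammatory genes (median 1.59) were higher in set 1 than in set 2 at this time, and the immediate early sum ran from 6940.5 to 51759 CPM over the 4 libraries, against 2813 to 11720.1 CPM in PBS. NRF2 targets, which defend against oxidants, rose in 14 of 19 with 0 down (15 up and 2 down adjusted over the list alone), including the cystine carrier gene Slc7a11 (7.02) and Srxn1 (2.21), and their shift was kept with an estimated correlation (adjusted p = 3.45e-14, then 0.00337). Integrated stress response genes rose in 8 of 17 (adjusted p = 6.85e-06, and 0.134 with an estimated correlation) and glycolysis genes in 12 of 24, with the glucose carrier gene Slc2a1 at 1.44 (adjusted p = 6.85e-06, and 0.450 with an estimated correlation). In the S phase list 16 of 26 were down and 0 up (21 down adjusted over the list alone), among them Uhrf1 (-3.12) and Mcm5 (-2.59) (adjusted p = 2.84e-08, and 0.450 with an estimated correlation). Of the LAM list 11 of 29 rose, with Mmp12 at 4.73. Among markers of other cells, the neutrophil list had 4 up, including S100a8 (3.45), and 1 down, G0s2 (-2.14), and the hepatocyte list 2 down (median -0.84, adjusted p = 0.000362, and 0.720 with an estimated correlation).

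The 2586 genes of 6 h included 515 up and 426 down by at least 2-fold. In set 1 alone 2917 genes passed, 1454 up and 1463 down, and in set 2 alone 1384. The count was 1489 without PBS 24 h replicate 1, 1704 without PBS 24 h replicate 2, 1610 without KC 6 h replicate 1 and 1538 without PBS 0 h replicate 2.

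**Figure D4:**
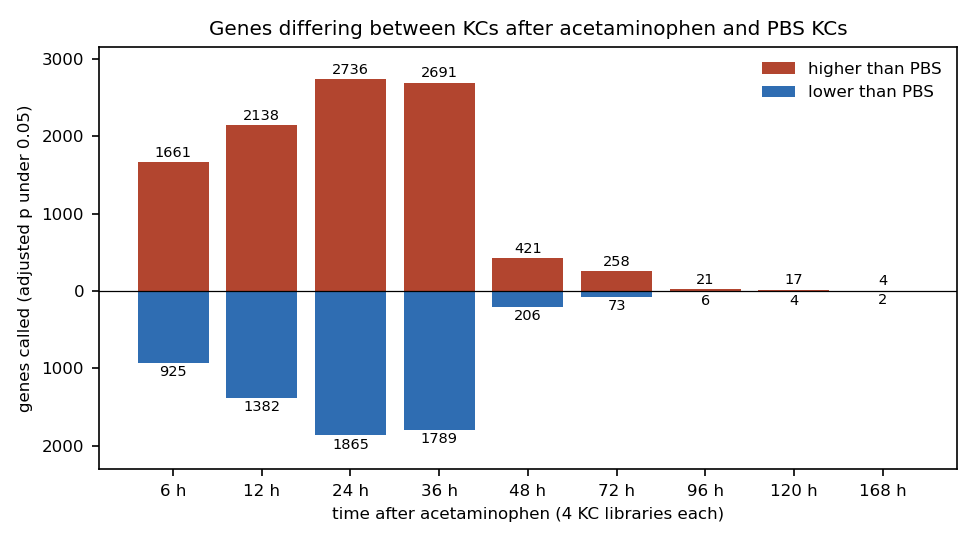
Number of genes called higher and lower in KCs than in PBS (vertical axis) at each time after APAP in hours (horizontal axis). Calls are most numerous at 24 h (2736 up, 1865 down) and 36 h (2691 up, 1789 down) and number 6 at 168 h.

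At 12 h 3520 genes differed, 2138 up and 1382 down. Mmp12, a macrophage elastase, rose by 6.60 (adjusted p = 1.38e-06), from 22.1 ± 7.03 (SD, n = 4) to 2101 ± 443 (SD, n = 4) CPM, and the stress cytokine gene Gdf15 by 6.5 (adjusted p = 0.000102), from 5.65 ± 3.72 (SD, n = 4) to 444 ± 313 (SD, n = 4) CPM. Cxcl3 (8.95, adjusted p = 0.000450) and the metalloprotease gene Adam8 (6.15, adjusted p = 0.000972) rose as well, with Cxcl3 at 0.0863 in set 2 alone. Marco rose by 3.09 (adjusted p = 5.90e-08), Gpnmb by 4.10 (adjusted p = 0.00531) and Cd9 by 1.78 (adjusted p = 0.00126). Trem2 rose by 1.08 (adjusted p = 0.0141), with 0.0741 without PBS 24 h replicate 1 and 0.0708 without PBS 0 h replicate 2. Il1b rose by 2.08 (adjusted p = 0.0212), with 0.0569 to 0.107 without any 1 of KC 12 h replicates 1 and 2 and the 4 PBS libraries. Clec4f fell by 0.65 (adjusted p = 0.00853). Thrsp (-5.63), Mup17 (-5.57), Car3 (-4.95) and the glucose-6-phosphatase gene G6pc (-4.82) fell, and none of the 4 passed in set 2 alone (0.105 to 0.277). Timd4 (-0.43, adjusted p = 0.0689), Vsig4 (-0.36, adjusted p = 0.0905) and Mki67 did not pass, but Timd4 passed without KC 12 h replicate 4 (adjusted p = 0.0275).

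Inflammatory genes rose in 25 of 26 at 12 h, including Clec4e (5.70) and Cxcl1 (5.67) (adjusted p = 2.97e-14, and 0.195 with an estimated correlation), and immediate early genes in 15 of 21. Of the 4 KC libraries 3 lie in set 1, where 25 of 26 inflammatory genes were higher (median 1.08 over set 2). Type I interferon genes fell in 25 of 29 with 0 up (2 up and 25 down adjusted over the list alone), among them Ifit3 (-2.38) and Ifi44 (-1.97), with adjusted p = 8.57e-19 and 0.0490 with an estimated correlation. MHC class I genes fell in 6 of 14 and class II genes in 5 of 13, with Ciita, the regulator of class II, at -2.54. Shifts kept with an estimated correlation were those of NRF2 targets (15 up and 1 down of 19, adjusted p = 0.00695), haem and iron genes (9 up and 0 down of 18, with Lcn2 5.28 and Hmox1 2.39, adjusted p = 0.0118), the integrated stress response (11 up and 1 down of 17, adjusted p = 0.0490) and glycolysis (15 up and 0 down of 24, adjusted p = 0.0490). LAM genes rose in 20 of 29 (adjusted p = 4.86e-10, and 0.195 with an estimated correlation). Growth factor genes rose in 5 of 20, among them Areg (6.95) and Osm (6.00). Cholesterol synthesis genes fell in 4 of 24 (adjusted p = 0.00471, and 0.503 with an estimated correlation). LXR targets had 3 up, such as Abca1 (0.91), and 1 down, and heat shock genes rose in 5 of 15. The hepatocyte list fell in 5 of 24 (adjusted p = 8.49e-05, and 0.526 with an estimated correlation) and 4 neutrophil genes rose, S100a9 by 4.32.

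Of the 3520 genes, 703 were up and 613 down by at least 2-fold. Set 1 alone, with 3 of the 4 KC libraries, gave 3093 genes, and set 2 alone, with 1, gave 873. The count was 2268 without PBS 24 h replicate 1.

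By 24 h 4601 genes differed, 2736 up and 1865 down. Mmp12 rose by 7.01 (adjusted p = 3.83e-07), to 2799 ± 2250.0 (SD, n = 4) CPM, Gdf15 by 5.55 (adjusted p = 0.000294), Gpnmb by 4.62 (adjusted p = 0.00138), Marco by 3.56 (adjusted p = 5.68e-09), to 6080.0 ± 3076 (SD, n = 4) CPM, Cd9 by 2.61 (adjusted p = 8.01e-06) and Trem2 by 1.30 (adjusted p = 0.00234). Clec4f stood at -1.09 (adjusted p = 2.18e-05, 6949 ± 2604 (SD, n = 4) CPM), Vsig4 at -0.84 (adjusted p = 6.95e-05) and Timd4 at -0.66 (adjusted p = 0.00361), while of the 23 KC identity genes 3 rose and 7 fell (adjusted p = 0.0575 for the list). Serpinb2, an inhibitor of plasminogen activators, rose by 4.72 (adjusted p = 0.0254), with 0.257 without KC 24 h replicate 1, 0.131 without PBS 24 h replicate 1 and 0.132 without PBS 0 h replicate 2. Mup17 (-5.84), Thrsp (-5.33), Keg1, a glycine acyltransferase gene (-5.07), and Car3 (-4.90) fell. In set 2 alone Gpnmb (0.105), Trem2 (0.126), Timd4 (0.0918), Mup17 (0.114) and Thrsp (0.138) did not pass. Spp1 (2.63, adjusted p = 0.0777), Il1b and Mki67 did not pass.

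S phase genes rose in 21 of 26 at 24 h with 0 down, among them Mcm2 (2.11) and Uhrf1 (2.07) (25 adjusted over the list alone, adjusted p = 1.38e-11, and 0.420 with an estimated correlation), while 0 of the 28 G2 and M phase genes passed in edgeR. Of the S phase genes 25 (median 0.87) and of the G2 and M phase genes 27 (median 1.72) were higher in set 2 than in set 1, and the G2 and M phase sum ran from 140.4 to 421 CPM over the libraries. Ribosomal protein genes rose in 30 of 30 (median 0.81, adjusted p = 5.76e-24, and 0.316 with an estimated correlation), oxidative phosphorylation genes in 18 of 31 and unfolded protein response genes in 9 of 18. Type I interferon genes fell in 23 of 29 (adjusted p = 2.85e-12, and 0.316 with an estimated correlation), MHC class II genes in 6 of 13 and complement genes in 9 of 16, against 3 up (adjusted p = 0.00171, and 0.420 with an estimated correlation). LAM genes rose in 19 of 29 and 1 fell, Tyrobp (-0.49), and 28 of the 29 were higher in set 1 than in set 2 (median 1.26). Inflammatory genes rose in 10 of 26 (adjusted p = 0.0104, and 0.660 with an estimated correlation), with all 26 higher in set 1 than in set 2 (median 2.84). Of lists for other cells, the hepatocyte list was down in 16 of 24 (20 adjusted over the list alone), with Alb at -1.57 and Cyp2e1 at -3.44 (adjusted p = 4.80e-08, and 0.472 with an estimated correlation). Its summed level fell from 4817 ± 1106 (SD, n = 4) to 1628 ± 316 (SD, n = 4) CPM. Haemoglobin genes such as Hbb-bs (-1.71) were among the 4 of 7 erythroid genes down, and the dendritic cell list had 2 of 13 down, Dpp4 (-2.33) and Tcf4 (-0.62). At least 2-fold changes numbered 875 up and 889 down. Set 1 alone gave 4439 genes and set 2 alone 2123, and no single library moved the count by more than 1.5 times.

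At 36 h 4480 genes differed, 2691 up and 1789 down, and genes of cell division were among the risers. Mki67 rose by 2.30 (adjusted p = 2.09e-05), from 20.4 ± 7.44 (SD, n = 4) to 99.2 ± 7.64 (SD, n = 4) CPM. The cell cycle transcription factor genes E2f7 (4.91, adjusted p = 0.00123) and E2f2 (4.62, adjusted p = 3.45e-05) and the mitotic gene Pimreg (4.63, adjusted p = 3.93e-05) rose. S phase genes were up in 26 of 26, with Ccne2 at 4.30 and Rrm2 at 4.26 (adjusted p = 7.86e-35, and 0.0656 with an estimated correlation), and G2 and M phase genes in 28 of 28, with Nusap1 at 4.57 and Bub1 at 3.94 (adjusted p = 1.23e-20, and 0.169 with an estimated correlation). Ribosomal protein genes rose in 30 of 30 (adjusted p = 6.55e-31, and 0.114 with an estimated correlation), oxidative phosphorylation genes in 29 of 31 (adjusted p = 7.17e-18, and 0.155 with an estimated correlation) and unfolded protein response genes in 12 of 18. Falls included Cd74, the class II invariant chain, at -2.51 among 8 of 13 class II genes down, 19 of 29 type I interferon genes down and 12 of 16 complement genes down, among them C1qb (-0.48). The inflammatory list had 1 riser, Ccl7 (1.83), with a median of 0.56 and a test that pointed down (adjusted p = 0.995).

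Mmp12 stayed high at 36 h (5.48, adjusted p = 4.05e-06), as did Marco (2.49, adjusted p = 5.03e-07), Cd9 (1.77, adjusted p = 0.000847) and Trem2 (1.20, adjusted p = 0.00474). Clec4f (-0.92, adjusted p = 0.000180) and Vsig4 (-0.75, adjusted p = 0.000257) were lower. Gpnmb rose by 3.48 (adjusted p = 0.0127), with 0.0667 without PBS 24 h replicate 2, 0.0650 without PBS 0 h replicate 1 and 0.0513 without PBS 0 h replicate 2. Timd4 fell by 0.50 (adjusted p = 0.0289), with 0.0746 and 0.0659 without KC 36 h replicates 1 and 2 and 0.0527 without PBS 0 h replicate 2. Mup17 (-7.16), the fatty acid hydroxylase genes Cyp4a10 (-6.29) and Cyp4a14 (-6.21), which are close copies, and Keg1 (-4.58) fell, as did 10 of 24 hepatocyte genes. Spp1 (2.01) and Il1b (-0.43) did not pass. At least 2-fold changes numbered 1123 up and 537 down, set 1 alone gave 2927 genes and set 2 alone 3684.

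At 48 h 627 genes differed, 421 up and 206 down, with mitotic and LAM genes among the risers. G2 and M phase genes were up in 27 of 28 (28 adjusted over the list alone, adjusted p = 1.38e-52, and 0.0155 with an estimated correlation), with Ccnb1, cyclin B1, rising by 4.47 (adjusted p = 0.000187), from 5.28 ± 6.78 (SD, n = 4) to 60.6 ± 16.6 (SD, n = 4) CPM. S phase genes were up in 4 of 26 (11 adjusted over the list alone). Mki67 rose by 2.46 (adjusted p = 0.000187), the spindle gene Aspm by 5.78 (adjusted p = 0.00229) and Pimreg by 5.11 (adjusted p = 0.000203). LAM genes rose in 11 of 29 (20 adjusted over the list alone, adjusted p = 2.81e-09, and 0.288 with an estimated correlation). Gpnmb rose by 5.79 (adjusted p = 0.00153), Cd9 by 2.15 (adjusted p = 0.00101) and Spp1 by 4.81 (adjusted p = 0.0107), with 0.102, 0.0694 and 0.107 for Spp1 without PBS 24 h replicate 1, PBS 0 h replicate 1 and PBS 0 h replicate 2. Complement genes fell in 8 of 16, among them C4b (-1.36) (adjusted p = 2.98e-11, and 0.0155 with an estimated correlation), and ribosomal protein genes rose in 21 of 30.

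Trem2 rose at 48 h by 1.39 (adjusted p = 0.00947), with 0.0705 without PBS 24 h replicate 1, 0.0767 without KC 48 h replicate 1 and 0.0877 without PBS 0 h replicate 2. Marco rose by 1.40 (adjusted p = 0.00877), with 0.0649 without PBS 24 h replicate 2 and 0.0720 without PBS 0 h replicate 1. Vsig4 fell by 0.55 (adjusted p = 0.0339), with 0.0769 to 0.159 without any 1 of 7 libraries, all but KC 48 h replicate 4. Clec4f (-0.51, adjusted p = 0.117) and Timd4 (-0.55, adjusted p = 0.0647) did not pass, but both passed without KC 48 h replicate 4 (0.0159 and 0.0222). Cyp4a14 (-6.07), Cyp4a10 (-5.01) and Keg1 (-4.12) fell, and Mup17 fell by 4.56 (adjusted p = 0.0450), with 0.0742 to 0.149 without any 1 of 7 libraries, all but KC 48 h replicate 4. The hepatocyte list had 2 of 24 down (8 adjusted over the list alone, adjusted p = 7.91e-10, and 0.399 with an estimated correlation). Il1b did not pass (0.68). Of the 627 genes, 220 were up and 75 down by at least 2-fold. With PBS 0 h as the control 52 genes were called. Calls numbered 979 in set 1 alone and 51 in set 2 alone. The count was 262 and 277 without PBS 24 h replicates 1 and 2, 175 without PBS 0 h replicate 2, and 285, 396 and 375 without KC 48 h replicates 1, 2 and 3.

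At 72 h 331 genes differed, 258 up and 73 down. The count was 33 with PBS 0 h as the control and 2 with the compared groups only. Of 29 LAM genes 19 rose and 0 fell (25 adjusted over the list alone, adjusted p = 4.42e-25, and 0.0398 with an estimated correlation). Of the 29, 28 were higher in set 1 than in set 2 (median 0.84), and the summed level ran from 8028 to 16175 CPM. All 11 mitochondrially encoded genes were likewise higher in set 1 (median 2.17), with sums from 4139 to 29714 CPM. Replicate 2 of this time lay far from replicates 1, 3 and 4 (squared difference over sampling variance of 133, 276 and 310.2 per gene, the last the highest within any group). Gpnmb rose by 8.59 (adjusted p = 6.45e-05), to 481 ± 482 (SD, n = 4) CPM, Trem2 by 2.41 (adjusted p = 5.43e-05), to 158 ± 87.1 (SD, n = 4) CPM, Cd9 by 2.80 (adjusted p = 8.11e-05) and Mmp12 by 4.64 (adjusted p = 0.000775). Spp1 rose by 5.23 (adjusted p = 0.0121), with 0.0572 to 0.127 without any 1 of KC 72 h replicate 1 and the 4 PBS libraries. Fatty acid oxidation genes rose in 6 of 21 (14 adjusted over the list alone), among them Angptl4 (2.21) and Cd36 (1.8), lysosome genes in 6 of 31, among them Ctsd (1.18), matrix genes in 6 of 18 and cholesterol synthesis genes in 3 of 24, such as Fdft1 (1.09). Under the preset correlation these lists shifted up (adjusted p = 4.65e-08, 6.98e-09, 9.14e-06 and 8.41e-07). With an estimated correlation they did not (adjusted p = 0.0615, 0.181, 0.0952 and 0.181). Of the G2 and M phase list 3 of 28 were up (10 adjusted over the list alone), with all 28 higher in set 1 than in set 2 (median 1.67) and sums from 206 to 683 CPM, and p53 targets had 2 of 16 up, Cdkn1a (2.56) and Phlda3 (2.29).

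RNA of other liver cells was also higher in some libraries of 72 h. Col1a1, a fibrillar collagen of stellate cells, rose by 7.74 (adjusted p = 0.000216), from 0.136 ± 0.170 (SD, n = 4) to 24.6 ± 29.7 (SD, n = 4) CPM, with Col3a1 (5.14), Col1a2 (4.95) and Lum (3.62) as the other risers of the 17 stellate cell genes (11 adjusted over the list alone, adjusted p = 0.00226, and 0.440 with an estimated correlation). The hepatocyte list summed to 10480.2 ± 13138 (SD, n = 4) CPM, with single libraries from 1746 to 29576 CPM. Cxcl13, a B cell attractant (-2.15, adjusted p = 0.0441), Cd207, langerin (-1.90, adjusted p = 0.0382), and Krt80 (-1.66, adjusted p = 0.0485) fell, and each call ended without any 1 of 7 libraries, all but KC 72 h replicate 4, with adjusted p of 0.0574 to 0.210, 0.0531 to 0.218 and 0.0780 to 0.175. Mup17 fell by 5.07 (adjusted p = 0.0441), with 0.0753 to 0.156 without any 1 of 7 libraries, all but KC 72 h replicate 2. Timd4 fell by 0.65 (adjusted p = 0.0382), with 0.108 to 0.155 without any 1 of KC 72 h replicates 1 and 2 and the 4 PBS libraries. Clec4f (-0.25), Vsig4 (-0.11), Marco (0.38), Mki67 (0.80) and Il1b (0.52) did not pass. Of the 331 genes, 136 were up and 24 down by at least 2-fold. Set 1 alone gave 1365 genes, 598 up and 767 down, and set 2 alone 128. The count was 95 and 60 without PBS 24 h replicates 1 and 2, 105 and 73 without PBS 0 h replicates 1 and 2, 85 without KC 72 h replicate 1, and 522 and 562 without KC 72 h replicates 3 and 4.

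**Figure D5:**
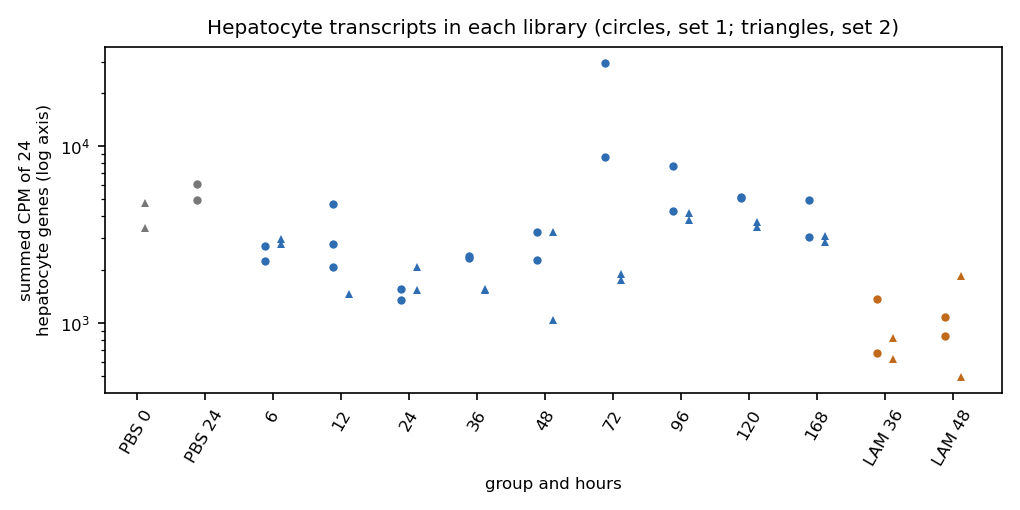
Summed CPM of the 24 hepatocyte genes on a log axis in each library, by group. The 72 h libraries span 1746 to 29576 CPM, and the LAM-like libraries of 36 h lie between 628 and 1358 CPM.

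Few genes differed from PBS after 72 h, genes of the circadian clock among them. At 96 h 27 genes differed, 21 up and 6 down. Arntl, which encodes the clock activator BMAL1, rose by 1.93 (adjusted p = 3.52e-05), from 15.1 ± 13.2 (SD, n = 4) to 38.8 ± 1.30 (SD, n = 4) CPM, and Ncapg2, a condensin subunit, by 1.45 (adjusted p = 3.52e-05). The clock output gene Tef fell by 1.40 (adjusted p = 0.0153) and the repressor gene Nr1d2 by 1.21 (adjusted p = 0.0274). The interferon-induced Rsad2 rose by 1.06 (adjusted p = 0.0219), the scavenger receptor gene Colec12 by 1.49 (adjusted p = 0.0449) and Gpnmb by 5.87 (adjusted p = 0.0131), and Mpp6 fell by 0.56 (adjusted p = 0.00628). Only Arntl and Ncapg2 of these stayed called in every fit that left out 1 library, and with PBS 0 h as the control Arntl had an adjusted p of 0.896. Adjusted p reached 0.154 for Rsad2 (without PBS 24 h replicate 1), 0.430 for Colec12 (without PBS 24 h replicate 2), 0.215 for Gpnmb (without PBS 24 h replicate 2), 0.128 for Tef (without KC 96 h replicate 3), 0.143 for Nr1d2 (without PBS 0 h replicate 2) and 0.114 for Mpp6 (without PBS 0 h replicate 1). Trem2, Spp1, Cd9, Clec4f, Timd4, Vsig4, Marco, Mki67 and Il1b did not pass. By list, LAM genes had 3 of 29 up, Gpnmb, Cd63 (3.04) and Colec12 (12 adjusted over the list alone, adjusted p = 1.28e-10, and 0.146 with an estimated correlation), type I interferon genes 1 of 29 (4 adjusted over the list alone, adjusted p = 2.59e-14, and 0.133 with an estimated correlation).

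The 27 genes of 96 h included 10 up and 5 down by at least 2-fold. Set 1 alone gave 85 genes. Set 2 alone gave 0 in edgeR, with 992 at an unadjusted p below 0.05, and PBS 0 h as the control gave 0, with 944, while DESeq2 on all libraries gave 75. The count was 3 and 6 without PBS 24 h replicates 1 and 2, 9 and 8 without PBS 0 h replicates 1 and 2, and 10, 14 and 8 without KC 96 h replicates 1, 2 and 3.

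At 120 h 21 genes differed, 17 up and 4 down. Rises of type I interferon genes were those of Rsad2 at 1.28 (adjusted p = 0.00389), from 98.4 ± 29.8 (SD, n = 4) to 231 ± 41.1 (SD, n = 4) CPM, the nucleotide kinase gene Cmpk2 at 0.93 (adjusted p = 0.00737) and Usp18 at 0.90 as 3 of 29 (15 adjusted over the list alone, adjusted p = 2.55e-25, and 0.0538 with an estimated correlation). Ncapg2 (1.09, adjusted p = 0.00666) and Snn (1.01, adjusted p = 0.0472) rose, and Nr1d1, the repressor REV-ERB alpha (-2.21, adjusted p = 0.0322), Nr1d2 (-1.28, adjusted p = 0.0241) and Wdr82 (-0.58, adjusted p = 0.0304) fell. Each of these calls ended without at least 1 library, with adjusted p up to 0.0652 for Rsad2 (without PBS 24 h replicate 1), 0.127 for Cmpk2 (without PBS 0 h replicate 2), 0.0715 for Ncapg2 (without PBS 0 h replicate 2), 0.327 for Snn (without PBS 0 h replicate 2), 0.223 for Nr1d1 and Wdr82 (without PBS 24 h replicate 1) and 0.142 for Nr1d2 (without KC 120 h replicate 1). Gpnmb did not pass (4.63, adjusted p = 0.0781), nor did the other fixed genes. Unfolded protein response and heat shock genes shifted down with 0 passing over all genes in edgeR and 9 of 18 and 8 of 15 down adjusted over the list alone (adjusted p = 5.79e-13 and 5.65e-08, and 0.175 for both with an estimated correlation). Of the 21 genes, 5 were up and 3 down by at least 2-fold. With PBS 24 h as the control 84 genes were called, 40 up and 44 down. Set 1 alone gave 233 genes, 109 up and 124 down, set 2 alone 0 in edgeR (723 at an unadjusted p below 0.05) and PBS 0 h as the control 0 (773), against 96 in DESeq2. The count was 1 and 2 without PBS 24 h replicates 1 and 2, 5 and 3 without PBS 0 h replicates 1 and 2, and 4, 9, 11 and 13 without KC 120 h replicates 1 to 4.

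At 168 h 6 genes differed, of which Arntl (1.85, adjusted p = 0.000104), Ncapg2 (1.01, adjusted p = 0.0205), Dennd2a (0.96, adjusted p = 0.0422) and the hyaluronan receptor gene Stab2 (0.63, adjusted p = 0.00398) were up and the clock genes Nr1d2 (-1.43, adjusted p = 0.0130) and Dbp (-2.23) were down. Cd63 at 96 h, Usp18 at 120 h, Dbp at 168 h and the PBS genes Mavs, Ptpn22 and Elmo2 are named outside the rule and were chosen after their values were seen. Arntl stayed called without any 1 library but not with PBS 0 h as the control (adjusted p = 1), and the others named by the rule did not, with adjusted p up to 0.260 for Ncapg2 (without PBS 24 h replicate 2), 0.842 for Dennd2a (without PBS 24 h replicate 1), 0.122 for Stab2 (without PBS 24 h replicate 1) and 0.170 for Nr1d2 (without KC 168 h replicate 2). None of the fixed genes passed, and Clec4f was at 14914 ± 250.1 (SD, n = 4) CPM. No program list had a gene past the threshold, and the largest shift was that of unfolded protein response genes (median -0.29, adjusted p = 1.87e-08, and 0.331 with an estimated correlation). Set 1 alone gave 35 genes, set 2 alone 0 in edgeR (813 at an unadjusted p below 0.05) and PBS 0 h as the control 0 (505), against 12 in DESeq2. The count was 2 without any 1 of KC 168 h replicates 1, 2 and 3, 1 without PBS 24 h replicate 1 or PBS 0 h replicate 1, and 3 without PBS 0 h replicate 2.

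Both PBS groups were also compared with each other, and 9 genes differed, 4 higher and 5 lower at 24 h than at 0 h. A fit on these groups only called 117 genes, 91 higher and 26 lower. The clock output gene Dbp was 3.09 higher (adjusted p = 0.0324), at 43.8 ± 9.04 (SD, n = 2) against 5.16 ± 1.40 (SD, n = 2) CPM, and the co-chaperone genes Dnaja1 (1.86, adjusted p = 0.0475) and Bag3 (1.72, adjusted p = 0.0324) and the antiviral adaptor gene Mavs (1.07) were higher as well. Arntl was 2.73 lower (adjusted p = 0.000116), at 3.96 ± 1.87 (SD, n = 2) against 26.2 ± 5.15 (SD, n = 2) CPM, as were the fatty acid carrier gene Fabp7 (-1.96, adjusted p = 0.000279), Tab1 (-1.49, adjusted p = 0.0457), Ptpn22 (-1.30) and Elmo2 (-0.93). Of 18 measured clock genes, in a list made after clock genes were seen among the calls, 1 rose and 1 fell, and 7 differed adjusted over the list alone. Heat shock genes rose in 2 of 15 (7 adjusted over the list alone, adjusted p = 8.38e-15, and 0.0510 with an estimated correlation). The groups had 2 libraries each, and PBS 24 h lies wholly in set 1 and PBS 0 h in set 2, so time and set could not be separated within this comparison. The count was 0 and 3 without PBS 24 h replicates 1 and 2, and 3 and 2 without PBS 0 h replicates 1 and 2, where the lone library of a group was assumed to vary like the other groups. Without PBS 24 h replicate 1 no call held, with adjusted p of 0.139 for Arntl and Fabp7.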

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

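A library was marked when its value lay far from the other libraries of its group, and 20 of 253 group values of fixed genes and marker sums were marked, where about 1 in 20 is likely from chance alone by the construction of the mark. The values below are CPM, given for the marked library and then for the range of the others of its group. KC 6 h replicate 1 had a lower Marco (1303 against 2221 to 2329) and a higher capsular macrophage sum (116 against 53 to 58.9). KC 12 h replicate 4 had an endothelial sum of 1033 against 833 to 861. KC 24 h replicate 1 had a capsular macrophage sum of 251 against 42.2 to 55.2, and replicate 2 had Ly6c2 at 0.314 against 0. At 36 h, KC replicate 2 had Spp1 at 2.12 against 1.14 to 1.22 and Ly6c2 at 0.493 against 0 to 0.0818, and replicate 3 had Mki67 at 87.8 against 102 to 104. KC 48 h replicate 4 had a neutrophil sum of 108 against 62.5 to 69.3. At 72 h, KC replicate 1 had Cd9 at 127 against 39.4 to 52.3, and replicate 4 had Marco at 961 against 551 to 589.

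At later times, KC 96 h replicate 1 had a hepatocyte sum of 7662 against 3804 to 4300 and Spp1 at 13.9 against 0.201 to 1.96, and replicate 4 had Marco at 1375 against 566 to 686. KC 120 h replicate 1 had Gpnmb at 92.6 against 9.14 to 10.7, replicate 2 had Ly6c2 at 1.13 against 0 to 0.0954, and replicate 4 had a platelet sum of 52.8 against 48.2 to 48.6. KC 168 h replicate 1 had a hepatocyte sum of 4982 against 2879 to 3118 and Ly6c2 at 0.0548 against 0, and replicate 3 had Trem2 at 29.9 against 19.8 to 20.8. Among the other named genes 70 of 825 pairs of gene and group were marked. The change of Ncoa4 between 36 and 48 h (1.12) was marked as the 1 call of the interaction.

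For the 3 patterns that follow, 7 tests were chosen only after the result was seen, while the 12 tests by splits were planned before. Immediate early and inflammatory genes were higher in set 1 than in set 2 among APAP groups, with 3120 genes differing, 1389 higher in set 1 and 1731 in set 2. Of the immediate early list 20 of 21 (median 1.42) and of the inflammatory list 22 of 26 (median 1.40) were higher in set 1, for example Jun (1.94), Fos (1.39), Nfkbia (2.02) and Tnf (3.87). A stronger injury in set 1 would be likely to fade by 120 and 168 h, yet the lower of the medians at those times was 0.776, which argues against injury as the whole cause. A ratio of mean totals of 1.0 argues against depth. Most immediate early genes were higher in set 1 in 11 of 11 APAP groups, which restates the pattern and so does not test whether handling may be its cause. Which difference between the sets lies behind it stays open.

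Genes of the circadian clock set the PBS groups apart and were called in KCs up to 168 h. If the sets caused this, the same genes would differ between the sets within APAP groups, but the median set difference there was -0.0372 times the median PBS difference, which argues against it. Over the 11 KC groups the mean log2 CPM of Arntl and Nr1d1, which peak at opposite hours of the day, were inversely related (Pearson r = -0.847, permutation p = 0.00132, Spearman rho = -0.60 with p = 0.0569, and r = -0.645 without the PBS 24 h and APAP 24 h groups). These groups include both PBS groups and differ in hours after APAP. The relation thus cannot tell the hour of collection from another change of the clock. The hour of collection is not in the labels and stays open, as does whether the calls of clock genes at any time, early or late, reflect APAP.

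Genes of liver enzymes fell in KCs from 6 to 48 h, in libraries whose hepatocyte RNA was lower too. Within groups the summed CPM of the falling genes followed the hepatocyte sum over 36 libraries of KCs after APAP (Pearson r = 0.826, permutation p = 6.0e-05, Spearman rho = 0.666 with p = 0.0008, r = 0.811 in set 1 and 0.777 in set 2, and 0.704 without KC 72 h replicates 2 and 4), so their RNA may come from hepatocytes. With the sum as a covariate 6, 6, 5, 6, 3 and 3 of 8 such genes were called at 6, 12, 24, 36, 48 and 72 h, against 6, 6, 7, 8, 5 and 1 without it. At 36 h the median change of the 8 genes minus that of the hepatocyte list was -2.91 on the log2 scale, but the genes were picked for their large falls, so this difference does not bear on the cause. Whether the content of hepatocyte RNA alone changed or hepatocytes also lowered these genes after APAP stays open.

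Splits put the counts beside those of every other grouping of the same sizes, or for the interaction only some. Fits held the compared libraries alone, with PBS as 1 group. The fit named compared groups only in the next part keeps the PBS groups apart, and its counts differ (2 against 8 at 72 h, 55 against 0 at 96 h, 128 against 12 at 120 h and 18 against 2 at 168 h). Real groups gave the highest of 35 counts at 6 h (1291, highest other 1), 12 h (3460, 0), 24 h (4630, 1), 36 h (4948, 2), 48 h (792, 1) and 72 h (8, 3), for LAM-like KCs at 48 h (268, 161) and for the interaction (3, 0). For LAM-like KCs at 36 h 2 of 35 splits reached the real 712. The other, by set (997), balances cell types and the rest gave 0, which argues against arbitrary grouping. The 8 splits parting every replicate pair alone are too few to tell. Here the split by set alone called more than the real groups at 96 h (31 against 0) and 120 h (136 against 12). So a set difference may exceed that of APAP there. At 168 h 1 other split, not that by set, called 27 against 2, so the calls there may not exceed those of an arbitrary grouping.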

How the results depend on the processing

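Set 1 only, set 2 only, both covariates, the header numbers and the libraries numbered 4 were alternatives chosen after seeing the data. For LAM-like KCs at 36 h, 322 genes became 1740 with the replicate block, 203 in set 1, 534 in DESeq2 and 712 with the compared groups only. At 48 h, 429 became 2054 with the block, 210 in set 1, 141 without the libraries numbered 4, 699 in DESeq2 and 268 with the compared groups only. The interaction count of 1 became 2 with RLE, with either covariate and in set 1 (sharing 0 genes with the main call), 43 with the block, 5 in DESeq2, 3 with the compared groups only and 0 in set 2 (758 at an unadjusted p below 0.05 in edgeR). The cause was not tested.

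For KCs at 6 h, 2586 became 1487 with PBS 24 h as the control, 1601 with PBS 0 h, 1384 in set 2 and 1189 with the compared groups only. At 12 h, 3520 became 2157 with PBS 24 h and 873 in set 2, at 24 h 4601 became 2123 in set 2, and at 36 h 4480 became 2838 with PBS 0 h and 2927 in set 1. At 48 h, 627 became 52 with PBS 0 h, 972 with the block, 979 in set 1, 51 in set 2, 1051 in DESeq2 and 948 with the compared groups only. At 72 h, 331 became 158 without the filter, 153 with PBS 24 h, 33 with PBS 0 h, 738 with the block, 1365 in set 1, 128 in set 2, 659 in DESeq2 and 2 with the compared groups only. The cause was not tested.

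At 96 h, 27 became 0 with PBS 0 h (944 at an unadjusted p below 0.05 in edgeR), 109 with the block, 85 in set 1, 0 in set 2 (992), 75 in DESeq2 and 55 with the compared groups only. At 120 h, 21 became 13 without the filter, 84 with PBS 24 h (40 up, 44 down), 0 with PBS 0 h (773), 76 with the block, 32 with either covariate, 233 in set 1 (109 up, 124 down), 0 in set 2 (723), 96 in DESeq2 and 128 with the compared groups only. At 168 h, 6 became 24 with PBS 24 h (11 up, 13 down, against 4 and 2), 0 with PBS 0 h (505), 35 in set 1, 0 in set 2 (813), 12 in DESeq2 and 18 with the compared groups only. Between the PBS groups, 9 became 3 with the header numbers, 25 in DESeq2 and 117 with the compared groups only (91 up, 26 down). The cause was not tested.

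Leaving out 1 library gave 179 to 314 genes for LAM-like KCs at 36 h, 149 to 561 at 48 h and 0 to 1 for the interaction. For KCs it gave 1489 to 2706 at 6 h, 2268 to 3583 at 12 h, 3260 to 4578 at 24 h, 3195 to 4222 at 36 h, 175 to 813 at 48 h, 60 to 562 at 72 h, 3 to 39 at 96 h, 1 to 13 at 120 h and 1 to 7 at 168 h, and 0 to 3 between the PBS groups. No alternative ended the calls of Nrp2, Cd36, Akr1b8, Cxcl14, Olfml3, Ifitm6, Plac8, Enpp2, C6, Ccl24, Ptgis, Adamdec1, Adcy4, Trem2, Clec4f and Timd4 at 36 h, nor of Cd36, Plac8, Adamdec1, Vipr1, Ifitm6, Gfra2, Asb2 and Trem2 at 48 h. DESeq2 gave no adjusted p for Mup17 at 6, 12, 24, 36, 48 and 72 h. RLE scaling kept every count of the comparisons but the interaction within 1.5 times, but moved the balance of rises and falls, from 1661 up and 925 down to 1477 and 1058 at 6 h and from 2736 up and 1865 down to 2391 and 2176 at 24 h.

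The replicate block was used for LAM-like KCs because libraries of the same number resembled each other in 16 of 16 cases, and beyond the values given with the results it changed no other call of a named gene there. PBS and APAP libraries share only a number (-0.276 to 0.213), and the block there has no such ground. It rests on the numbers of the labels, which differ from the headers for PBS 0 h, and with the header numbers the counts of 48, 72, 96 and 120 h were 737, 347, 26 and 18, close to 627, 331, 27 and 21 without a block. Of the list shifts 437 kept their verdict with the block, 54 became stronger, 15 weaker and 1 reversed, the T and NK cell list in LAM-like KCs at 48 h (down with adjusted p = 0.0339, and with the block up with 0.952, or 0.954 with an estimated correlation as well), for which the cause was not tested. In the interaction the block brought past the threshold the shifts down of inflammatory (1.43e-13), immediate early (2.95e-05), complement (2.95e-05), clearance (0.00147), matrix (0.0200) and interferon genes (0.0251), with 0.213, 0.683, 0.443, 0.451, 0.623 and 0.799 in that order with an estimated correlation as well. It did so for the shifts up of S phase (0.0182), heat shock (0.0200), monocyte (0.0294) and cholesterol synthesis genes (0.0499), with 0.840, 0.623, 0.569 and 0.623. With an estimated correlation 195 camera calls were lost and 312 verdicts stayed, and with the block as well 192 were lost and 314 stayed, since correlated genes carry less evidence.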

Other observations

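Marker sums of other cell types gave values outside the comparisons. Pf4 made up most of the platelet sum, which was 261 ± 22.8 (SD, n = 4) CPM in LAM-like KCs at 36 h and 188 ± 59.4 (SD, n = 4) CPM at 48 h, against 58.5 ± 9.01 (SD, n = 4) CPM in PBS. The erythroid sum was 23.4 ± 5.42 (SD, n = 4) CPM in PBS and 5.97 ± 2.25 (SD, n = 4) CPM in KCs at 24 h. The endothelial sum was 874 ± 126 (SD, n = 4) CPM in PBS and the stellate cell sum 298 ± 50.1 (SD, n = 4) CPM, against 725 ± 654 (SD, n = 4) CPM at 72 h.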
